A study of Homo sapiens with 8 samples.

How the data were processed

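CUT&RUN libraries of RH4 and RH30 cells were analysed from the authors' deposited peak lists: 2 RH4 lists (NFYB, NFYC), 4 RH30 NFYB lists (sgCtrl1, sgCtrl2, sgCCAAT2a, sgCCAAT2b), 1 RH4 consensus list and 3 differential tables, 10 files in all. No reads or signal were used, and the 2 IgG libraries were not analysed here. Per the labels' protocols, RH30 cells were transduced with guide RNAs, selected with blasticidin, and given rapamycin to start editing; the term seBE in the titles is not explained there. Libraries were grouped by title. The 5 libraries titled RH30 have RH4 as source name and cell line; the design text and treatment protocol go with the title.

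The values in these files are peak positions in bp, deposited by the authors without peak heights. Column 5, where a score would stand, holds a constant of 1 in all 10 deposited files, so peaks could not be ranked or filtered by a score. Per the file headers, RH30 peaks were called per library with HOMER findPeaks in factor style. The calls required 2-fold more tags than an input directory (S3) and 4-fold more than the surrounding 10000 bp, with a Poisson p over input of 0.0001 and a clonal filter of 2. The same input was named for all 4 libraries, and the headers do not say which library it was. Per the file headers, the input filter removed 99.5%, 98.0%, 99.5% and 99.4% of putative peaks for sgCtrl1, sgCtrl2, sgCCAAT2a and sgCCAAT2b. How far the lists depend on that input was not tested. The headers name 15 columns, which the deposited entries do not hold. Per the file headers, the differential tables come from HOMER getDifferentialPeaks on the sgCtrl2 list, with a fold of 2.5 and a Poisson p of 0.001, and hold peaks higher in sgCtrl2. Every entry of these tables was identical to an sgCtrl2 peak. The caller of the RH4 lists is not given in the sources used here. Their entries carry another set of coordinates, whose start differed in 3213 of 3243 NFYB and 3730 of 3760 NFYC entries, which points to a conversion from another build by the authors. Per the submitters' processing notes, FastQC, Trimmomatic, Bowtie2, MACS2, bedtools, HOMER and deepTools and the build hg38 were used, with no versions or roles given.

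Per the file headers, the RH30 libraries held 10.5 to 28.2 M tags. Depth is unknown for RH4. Exact Clopper-Pearson 95% intervals cover the counting of peaks or genes only, since each guide and antibody has 1 library. Controls and edited libraries, 2 against 2 with a guide each, were compared by their values, and no p-value between conditions was computed.

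Peaks were called shared when they overlapped by at least 1 bp. Chance levels came from 100 random placements of a list on its chromosomes (20 for pairs of lists), up to the last protein-coding gene end. Genes were the 20033 protein-coding genes of the RefSeq table for GRCh38.p14, which holds no strand and no sequence. A gene was counted when a peak overlapped the window of 1000 bp either side of either of its ends. The 13 gene lists were fixed before the data were examined and set against 10000 random lists of the same size. The percentile is the percent of random lists with fewer genes. Gene density within 100 kb, in 10 groups, was a further matching chosen after seeing the data. Distances to gene ends were counted in bins of 50 bp. In the RH30 files the order of entries follows the number in the peak name within each chromosome (median Spearman rho 0.983, 0.940, 0.961 and 0.961 for sgCtrl1, sgCtrl2, sgCCAAT2a and sgCCAAT2b), and order was used as a stand-in for rank. To compare genes or peaks of a like place, each was exchanged at random for another within 250 places, 10000 times.

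Named genes followed a rule fixed at the same time: PAX3 and FOXO1; at most 6 members of each list, those in most libraries first and then alphabetical; the 10 genes with the widest consensus entries; the 10 genes of highest place listed over both edited libraries and not over sgCtrl1; and the 10 of highest place in all 4 RH30 lists. A promoter shared by neighbouring genes counted once. Other genes were named after their values were seen, as stated there.

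The plan was changed where the reference or the files did not allow it. CCAAT motif shares and positions were not run, since no genome sequence was used here. The window around the transcription start became a window around either gene end. Random lists were not matched on GC content. The planned highest scored part of each list was replaced by the widest entries in RH4 and by the first entries in file order in RH30, and the tie in width among RH30 genes was broken by file order.

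Alternatives were windows of 500 and 3000 bp, a shared overlap of 50% of both peaks, the peak centre in the window, the stricter parts of the lists, and, chosen after seeing the data, primary chromosomes only and sgCtrl2 peaks also found in sgCtrl1 or RH4 NFYB. The overlap code was tested on simulated lists: 60 of 60 counts matched bedtools 2.31.1, and a list with 50 percent of sgCtrl2 peaks copied in gave an overlap of 49.99% of 6687 peaks. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.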

Results

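Binding of the CCAAT-binding factor NF-Y was profiled by CUT&RUN, in which a nuclease tethered to an antibody releases the DNA around a bound protein for sequencing. NF-Y is a trimer of NFYA, NFYB and NFYC. The cells were RH4 and RH30, established rhabdomyosarcoma lines that carry the PAX3-FOXO1 fusion oncogene. Uninfected RH4 cells gave 1 library each with antibodies to NFYB, NFYC and IgG. RH30 cells carried an inducible cytosine base editing system and were collected on day 8. They received 1 of 4 guide RNAs: the controls sgCtrl1 and sgCtrl2, or sgCCAAT2a and sgCCAAT2b, which target a CCAAT motif in the promoter of the endogenous PAX3 gene. The libraries of these 2 guides are called edited here; editing itself was not analysed here. Each RH30 guide gave 1 NFYB library, and sgCtrl1 also gave 1 IgG library. The 8 libraries form 8 groups of 1, so no guide or antibody has a replicate. Controls and edited libraries can be set side by side as 2 against 2, each with a guide of its own. Peak lists of the 6 NFYB and NFYC libraries were analysed; the 2 IgG libraries were not analysed here. The 5 libraries titled RH30 carry RH4 as source name; they are called RH30 here, after their titles and the design description.

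Per the file headers, the RH30 NFYB libraries held 13.9 M tags with sgCtrl1, 10.5 M with sgCtrl2, 21.2 M with sgCCAAT2a and 28.2 M with sgCCAAT2b. The share of tags in peaks was 2.40%, 3.10%, 1.22% and 1.46% in the same order. The lists held 4025, 6687, 2451 and 2558 peaks. Both edited libraries were thus the deepest and had the lowest share of tags in peaks. The RH4 lists held 3243 NFYB and 3760 NFYC peaks, and the depth behind them is unknown.

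The first question was whether NF-Y was found at the PAX3 promoter and whether guides against its CCAAT motif changed that. PAX3, a transcription factor of muscle progenitors and the N-terminal part of the fusion oncoprotein, carried an NF-Y peak at its promoter in RH4 cells and in both RH30 controls, and in neither edited library. On chromosome 2 of hg38 the gene spans positions 222199887 to 222298998, with its 5' end at the higher coordinate. The NFYB peak of RH4 lay at 222298920 to 222299147 and the NFYC peak at 222299050 to 222299142. In RH30 the peak lay at 222299014 to 222299202 with sgCtrl1 and at 222299005 to 222299201 with sgCtrl2, centred 110 bp and 105 bp upstream of the gene. The sgCCAAT2a and sgCCAAT2b lists had 0 peaks within 1000 bp of this gene end, and 0 within 100 kb of the gene. Within 100 kb the RH4 NFYB, RH4 NFYC and sgCtrl1 lists each held 1 peak, the promoter peak itself, and the sgCtrl2 list held 4. The authors' deposited tables of differential peaks listed the PAX3 peak as higher in sgCtrl2 than in sgCCAAT2a and than in sgCCAAT2b. The authors' deposited table of sgCtrl2 over sgCtrl1 did not list it.

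**Figure D1:**
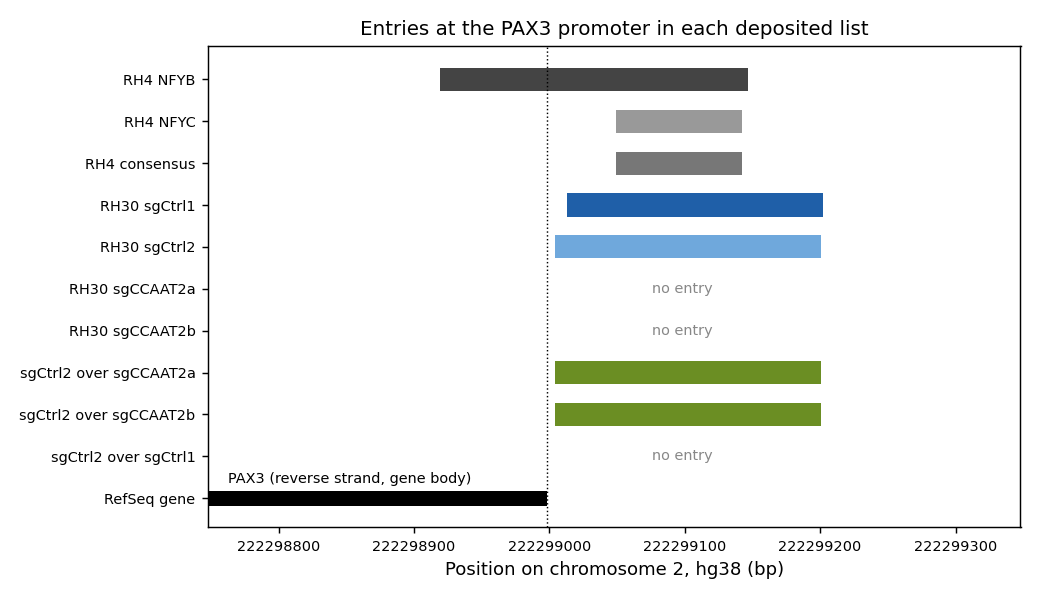
Entries of each deposited list at the PAX3 promoter, on chromosome 2 of hg38 in bp; a bar is 1 entry, the dotted line is the 5' end of the gene at 222298998, and the lower bars named "over" are the authors' deposited tables of peaks higher in sgCtrl2. The RH4 lists and both RH30 controls have an entry and the sgCCAAT2a and sgCCAAT2b lists have none.

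The edited libraries lost calls elsewhere too, so the PAX3 peak was set beside control peaks of a like place in the file. The PAX3 peak stood at place 703 of 6687 in the sgCtrl2 list and at place 545 of 4025 in the sgCtrl1 list. Of the 469 sgCtrl2 peaks within 250 places that also overlapped an sgCtrl1 peak, 14 (2.99%, 95% exact interval 1.64 to 4.96%) had no edited peak within 1000 bp. The share was 2.65% within 100 places and 5.04% within 500 places. From the sgCtrl1 list it was 0 of 180, 0.887% of 451 and 1.32% of 906 peaks within 100, 250 and 500 places. Being listed over both edited libraries and not over sgCtrl1 was more common, at 30.7% of the 469 peaks in the authors' deposited tables. These neighbourhoods were chosen after the lists had been seen, and the headers do not state that file order ranks peaks.

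FOXO1, the other partner of the fusion, had a peak at its 5' end in the RH4 NFYC list and in the RH30 sgCtrl2 list only. The gene spans positions 40555667 to 40666641 of chromosome 13, the NFYC peak lay at 40666617 to 40666762, and the sgCtrl2 peak lay at 40666658 to 40666854. No FOXO1 peak was called for NFYB in RH4, with sgCtrl1 or with either CCAAT guide. In the authors' deposited tables the FOXO1 peak was listed as higher in sgCtrl2 than in sgCCAAT2a and sgCCAAT2b, and not than in sgCtrl1. As sgCtrl1 also lacked the peak, its absence from the edited lists does not set these apart from the controls.

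In RH4 cells the NFYB and NFYC subunits were found largely at the same places. Of the 3243 NFYB peaks, 89.1% (88.0 to 90.1%) overlapped an NFYC peak, and of the 3760 NFYC peaks, 81.6% (80.4 to 82.9%) overlapped an NFYB peak. Random placement along whole chromosomes gave at most 0.247% and 0.239%. It did not keep peaks at gene ends, where most peaks of both lists lay, so this is a low bar. How far the overlap exceeds that of unrelated lists at gene ends was not tested. The deposited consensus list of 3073 entries equalled the intersections of the NFYB and NFYC peaks in 3073 of 3073 cases. The widest consensus entries at genes lay at the imprinted gene PEG3 with its neighbour ZIM2 (969 bp), at CIC, a transcriptional repressor (965 bp), and at PPM1B, a protein phosphatase (865 bp). They were followed by MLEC (814 bp), MYL11 with TBC1D10B (805 bp), RAB40C (791 bp) and R3HDM1 with ZRANB3 (789 bp). CKS1B, a cyclin-dependent kinase subunit, with SHC1 (776 bp), BLOC1S3 with TRAPPC6A (734 bp) and SERTAD3 (710 bp) completed the first 10. The overlap depended on how much of a peak had to be shared: with 50% of both peaks it was 53.7% of NFYB and 46.3% of NFYC peaks, and the median widths were 411 bp and 190.5 bp.

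NF-Y peaks concentrated just outside the ends of protein-coding genes in all 6 libraries. Without strand, a window of 1000 bp either side of each end of a gene was used. In RH4, 77.2% (75.7 to 78.6%) of NFYB peaks and 73.7% (72.2 to 75.1%) of NFYC peaks overlapped such a window. In RH30 the share was 53.3% (51.8 to 54.9%) with sgCtrl1, 43.3% (42.1 to 44.5%) with sgCtrl2, 60.6% (58.6 to 62.5%) with sgCCAAT2a and 59.9% (58.0 to 61.8%) with sgCCAAT2b. Random placement gave mean shares from 3.42 to 4.13%. The median peak centre within the window lay from 74 to 92 bp outside the gene, and the fullest 50 bp bin ran from 50 to 100 bp in every library. Lists with more peaks had lower shares in RH30: in the first 3343 sgCtrl2 peaks in file order the share was 72.3%, and in the last 3344 it was 14.4%.

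**Figure D2:**
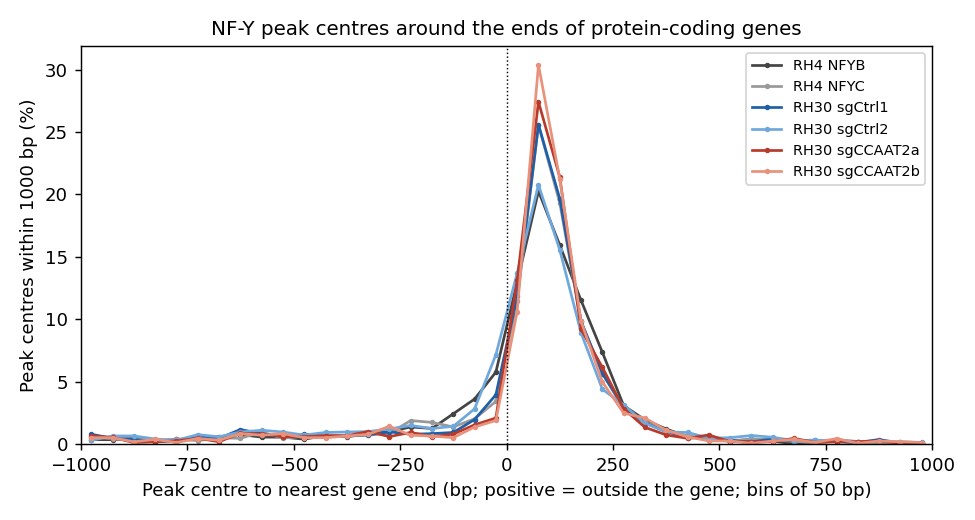
Distance in bp from the centre of each peak to the nearest end of a protein-coding gene, positive outside the gene, as a percent of the centres within 1000 bp in bins of 50 bp; each line is 1 library. All 6 lines peak in the bin from 50 to 100 bp outside the gene.

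Genes of protein folding in the endoplasmic reticulum, cholesterol synthesis and the cell cycle carried NF-Y at their ends far more often than random gene lists of the same size. In the RH4 consensus, 18 of 20 genes of endoplasmic reticulum stress and folding had a peak (90%, 68.3 to 98.8%), against a median of 3 and a highest value of 9 in 10000 random lists. They include the chaperones CALR and CANX, the co-chaperones DNAJB11 and DNAJC3, and CRELD2 and EDEM1, all with a peak in all 6 libraries. Cholesterol and fatty acid synthesis had 14 of 20 genes with a peak (70%, 45.7 to 88.1%), among them HMGCS1, FDPS, MVD, MVK and SC5D. The G2/M and S phase list also had 14 of 20, with the mitotic kinase genes AURKA and CDK1, the cyclin gene CCNB2, CDC20, CDC25A and CDC6 in all 6 libraries. For these lists the highest random values were 9 and 10. Both RH30 controls together gave 15, 12 and 12 of 20 genes, above every random list, which reached at most 9. Random lists came from all 20033 protein-coding genes and were not matched on GC content or expression. How far the excess is particular to these pathways was therefore not tested.

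Serine synthesis, NF-Y and histone genes also stood above most random lists, while ribosomal protein and heat shock genes stood lower. Serine, one-carbon and amino acid synthesis had 6 of 10 genes with a consensus peak, at percentile 99.92 of the random lists, including ATF4, a regulator of amino acid synthesis, MTHFD1, MTHFD2, PSAT1 and PSPH. Of the NF-Y subunits and partners 5 of 8 had one, at percentile 99.85, namely NFYA, NFYB, NFYC, SP1 and SP3. NFYA, NFYC, SP1 and SP3 had a peak in all 6 libraries, whereas NFYB had a peak in both RH4 libraries and with sgCtrl1 only. Replication-dependent histone genes had 23 of 69 (33.3%), at percentile 99.99, with H1-2, H1-4, H2AC17, H2AC20, H2AC21 and H2AC4 in all 6 libraries. With random lists matched on gene density the median rose from 9 to 13 and the percentile was 99.82. Neighbouring histone genes share windows and peaks, so these are not independent counts. With the widest RH4 entries only the share was 15.9%, and in both RH30 controls it went from 37.7% to 11.6% with the first entries in file order. Ribosomal protein genes had 16 of 85 (18.8%), at percentile 90.2, and 19 of 85 for NFYB alone in RH4, at percentile 95.2. Matched on gene density these percentiles were 80.0 and 88.8. RPL13, RPL13A, RPL3L, RPLP0 and RPS2 had a peak in all 6 libraries. Heat shock genes had 2 of 12, at percentile 50.7: HSPA8, a constitutive chaperone, had a peak in all 6 libraries, HSPH1 in 4 and HSP90AA1 in 1.

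Muscle genes were not enriched. Of 25 myogenic genes 3 had a consensus peak, at percentile 33.3, and 5 had one in both RH30 controls, at percentile 86.1. Among them were PAX3, SIX4, MEF2D and MYOD1, the last a master regulator of muscle identity; CKM had a peak for NFYB in RH4 only. Of 20 reported PAX3-FOXO1 target genes 1 had a consensus peak, at percentile 6.17, and 2, ALK and MYOD1, had one in both RH30 controls. FGFR4 and MET had a peak with sgCtrl2 only. MHC class II genes (0 of 10), blood cell markers (0 of 12) and liver cell markers (0 of 10) had none in any of the 6 libraries. A list of 10 with 0 hits allows a share of up to 30.8% at the upper 95% exact limit, and a list of 12 up to 26.5%.

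**Figure D3:**
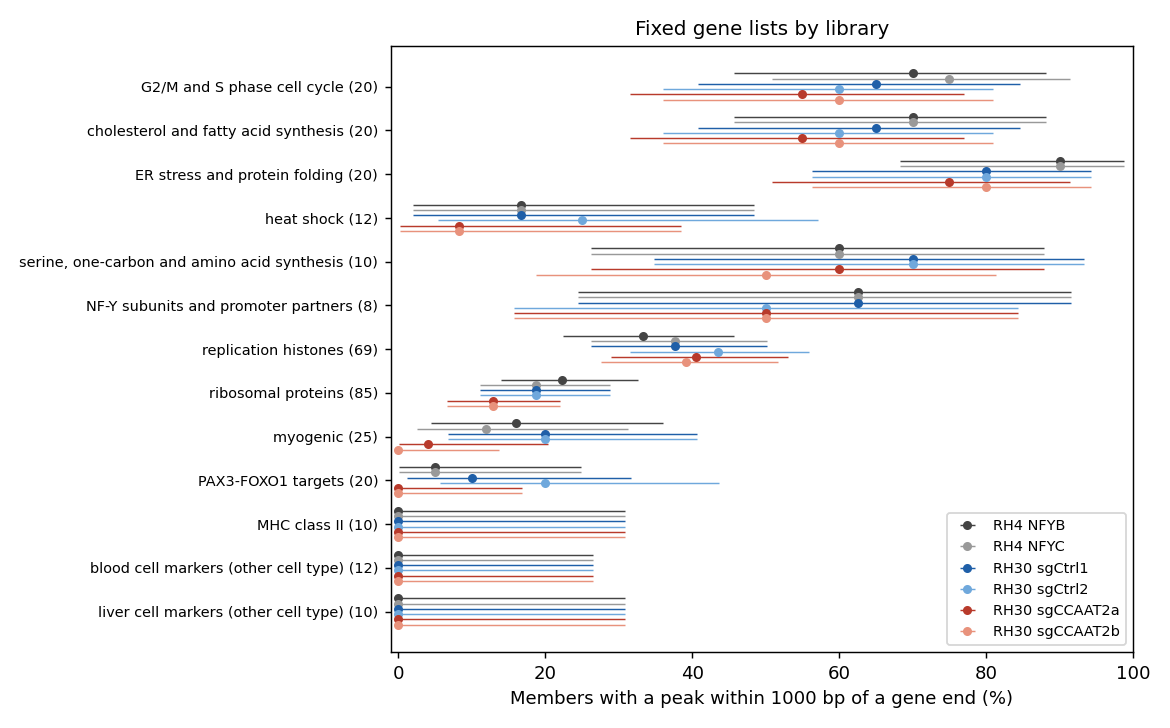
Percent of the members of each fixed gene list that had a peak within 1000 bp of a gene end in each library; points are shares, lines are exact 95% intervals that cover counting of genes only, and the number of members stands in parentheses. Endoplasmic reticulum genes had 18 of 20 members with a peak in both RH4 libraries, and MHC class II, blood and liver markers had 0 in all 6 libraries.

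Most RH4 NFYB peaks, and most genes with one at an end, were shared with each RH30 control, where the same antibody was used. Of the RH4 NFYB peaks 71.3% (69.7 to 72.8%) overlapped an sgCtrl1 peak and 73.8% (72.2 to 75.3%) an sgCtrl2 peak. Conversely, 57.6% of sgCtrl1 and 35.8% of sgCtrl2 peaks overlapped an RH4 NFYB peak. Of the 3010 genes with an RH4 NFYB peak at an end, 2188 also had one with sgCtrl1 and 2297 with sgCtrl2, where independent sets would share 379 and 505. A peak at 1408 of 20033 protein-coding genes was found in all 6 libraries. RH4 NFYB peaks are wider than RH30 peaks, and with 50% of both peaks required the shares of RH4 NFYB peaks fell to 18.3% and 24.3%.

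In RH30 most peaks of each edited list overlapped a peak of each control list. Of sgCCAAT2a peaks 83.4% (81.8 to 84.8%) and of sgCCAAT2b peaks 84.5% (83.1 to 85.9%) overlapped an sgCtrl1 peak. The shares that overlapped an sgCtrl2 peak were 79.8% and 80.7%. Between the edited lists, 85.8% of sgCCAAT2a peaks overlapped an sgCCAAT2b peak. The background between the controls was wide: 64.4% (62.9 to 65.9%) of sgCtrl1 peaks overlapped an sgCtrl2 peak and 38.8% (37.6 to 40.0%) of sgCtrl2 peaks an sgCtrl1 peak. Of sgCtrl1 peaks 50.7% overlapped an sgCCAAT2a and 53.7% an sgCCAAT2b peak. Of sgCtrl2 peaks 29.2% overlapped an sgCCAAT2a and 30.9% an sgCCAAT2b peak. Shares of lists of unlike length cannot be compared directly. For each control list, fewer peaks overlapped an edited list than the other control list, but the edited lists were also the shortest. Among the 2594 sgCtrl2 peaks that also overlapped an sgCtrl1 peak, 1665 (64.2%) overlapped a peak of both edited lists and 589 (22.7%) of neither. The first peaks of the file were shared by all: of the first 668 sgCtrl2 peaks 90.6%, 91.2% and 90.7% overlapped an sgCtrl1, sgCCAAT2a and sgCCAAT2b peak, and of the last 669 it was 2.24%, 1.49% and 2.09%. The highest placed sgCtrl2 peaks at genes that were found in all 4 RH30 lists lay at DRC3 with TOM1L2, TOMM40, a mitochondrial import channel, KPNB1, a nuclear import receptor, FBXO24 with LRCH4, CCNK, MTMR4, AGFG2, UBALD2, AP2A1 and KMT5C.

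Most sgCtrl2 peaks were listed as higher than in each edited library, and many were also listed as higher than in the other control. It was not most among peaks shared by the controls: of sgCtrl2 peaks also in sgCtrl1, the authors' deposited tables listed 39.2% over sgCCAAT2a and 32.3% over sgCCAAT2b. The authors' deposited tables list sgCtrl2 peaks with at least 2.5-fold more tags and a Poisson p of at most 0.001 between single libraries. The authors' deposited table over sgCCAAT2a held 4136 peaks (61.9% of the sgCtrl2 list), that over sgCCAAT2b 4057 (60.7%) and that over sgCtrl1 2422 (36.2%). The authors' deposited tables over sgCCAAT2a and sgCCAAT2b shared 3505 peaks, where independent tables would share 2509. Both use the same sgCtrl2 library, and the part of the excess due to that library cannot be split off. Listed over both edited libraries and not over sgCtrl1 in the authors' deposited tables were 1627 peaks, with 1878 in all 3 tables and 1789 in none. Among sgCtrl2 peaks also in sgCtrl1 the 1627 became 690. The control comparison differed most by place: of the first 3343 sgCtrl2 peaks, 9.96% were listed over sgCtrl1 in the authors' deposited tables, against 50.8% over sgCCAAT2a and 45.4% over sgCCAAT2b. Of the last 3344 peaks the authors' deposited tables listed 62.5%, 72.9% and 75.9%.

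**Figure D4:**
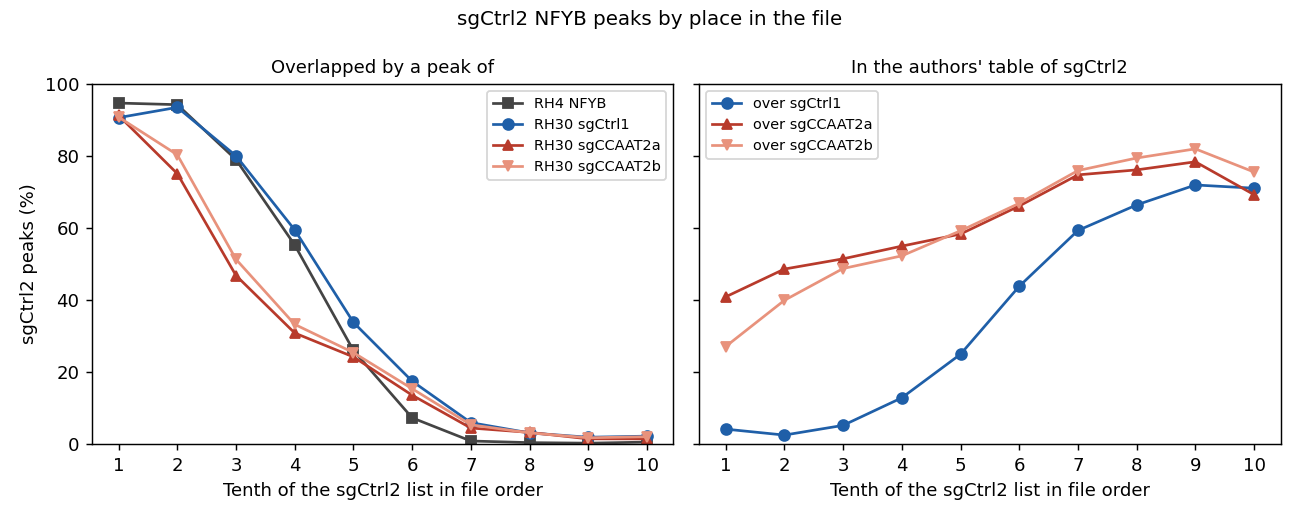
Percent of sgCtrl2 peaks, in 10 equal parts of the list in file order, that overlapped a peak of another library (left) and that stood in the authors' deposited tables of peaks higher in sgCtrl2 than in the named library (right). Overlap with sgCtrl1 fell from 90.6% to 2.24% from the first to the last part, and the share listed over sgCtrl1 went from 4.19% to 71.0%.

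The highest placed genes listed over both edited libraries and not over sgCtrl1 in the authors' deposited tables were CCNK, a cyclin that partners transcriptional kinases, CIC, BCL2L1, an inhibitor of apoptosis, and BMAL1, a circadian transcription factor. FER, PRKACA, the catalytic subunit of protein kinase A, SFXN5, PGP, HMG20B and NAPA followed. A listing did not mean that the peak was gone: 7 of these 10 still had a peak in both edited lists, CIC and SFXN5 had one with sgCCAAT2b and not with sgCCAAT2a, and BCL2L1 had one in neither. The sgCtrl1 list also lacked the peaks at CIC, SFXN5 and BCL2L1, so their absence does not set the edited lists apart from the controls.

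Among 2258 genes with a peak at an end in both RH30 controls, 1496 (66.3%) had one in both edited libraries and 489 (21.7%) in neither. Endoplasmic reticulum genes had a peak in both edited libraries in 13 of 15 cases, cell cycle genes in 10 of 12 and cholesterol genes in 9 of 12. Ribosomal protein genes had one in 9 of 12, serine and one-carbon genes in 5 of 7, NF-Y and partner genes in 4 of 4 and heat shock genes in 1 of 2. Absent from both edited lists were 0, 1, 1, 2, 1, 0 and 1 genes in the same order. Expected from genes of a like place in the sgCtrl2 file were 0.524, 1.57, 1.51, 3.05, 1.57, 0.0863 and 0.159. As few absent came up in 36.2 to 99.5% of draws, so none of these lists stood out from genes of a like place. With so few absent expected, the draws could hardly show that a list kept its peaks beyond what place would give. Endoplasmic reticulum genes and NF-Y and partner genes had 0 absent, the lowest count possible, and 57.7% and 91.6% of draws matched it. Whether these lists kept peaks beyond their place was therefore not decided. Genes absent from both edited lists include KIF23 in the cell cycle list, PHGDH, an enzyme of serine synthesis, RPL14 and RPL18, and HSPH1, all named after their values were seen. None of 5 myogenic genes had a peak in both edited libraries: PAX3, MYOD1, MEF2D and SIX4 had none in either. Genes with a like place in the sgCtrl2 file would give 1.52 absent, and 1.5% of 10000 draws gave as many as 4. PAX3 is the locus the guides target; without it 3 of 4 were absent where 1.48 were expected, and 13.0% of draws gave as many. Both PAX3-FOXO1 target genes with control peaks, ALK and MYOD1, were absent from both edited lists, and 22.5% of draws gave as many. Histone genes had a window with a peak in both edited libraries in 25 of 26 cases, all but H4C2. Of the 14 sgCtrl2 peaks in these windows that themselves overlapped an sgCtrl1 peak, 10 were in both edited lists and 4 in neither, where 5.22 absent were expected. The count by gene takes any peak in the window, so it does not carry over to single peaks.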

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

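Of 135 alternatives, 74 left the result the same and 61 moved it. A share counted as the same when it stayed within the exact 95% interval of the first value, and a count when it stayed within 1.5-fold. The intervals of short gene lists are wide, so large shifts there still count as the same. No paired analysis was possible because each group has 1 library. For the gene lists 46 of 52 stayed within that tolerance, which does not mean that they held still. The MHC class II, blood and liver lists, at 0%, could only stay the same, since these alternatives narrow the window or the peak lists. The count of peaks listed over both edited libraries and not over sgCtrl1 rests on identical entries, so a shared overlap of 50% could not move it. With the widest RH4 entries the serine and one-carbon list went from 60 to 30% and the cell cycle and cholesterol lists from 70 to 50%. With the first RH30 entries the myogenic list went from 20 to 12% and the PAX3-FOXO1 targets from 10 to 5%. Of the 1627 peaks listed over both edited libraries and not over sgCtrl1 in the authors' deposited tables, 1092 were among the first 3343 places. CCAAT shares, GC matching and parts of the lists by score were planned and not run, for want of a sequence and of scores. Alternatives on file order, on primary chromosomes and on sgCtrl2 peaks also found elsewhere were chosen after seeing the data.

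Requiring 50% of both peaks lowered every overlap that moved. In RH4 it gave 53.7% of NFYB and 46.3% of NFYC peaks, and 56.8% and 97.2% of consensus entries against NFYB and NFYC. In RH30 it gave 56.9% of sgCtrl1 in sgCtrl2 and 34.2% of sgCtrl2 in sgCtrl1, 24.8% and 26.4% of sgCtrl2 in sgCCAAT2a and sgCCAAT2b, and 48.0% and 48.8% of sgCtrl1 in these. It gave 81.9% of sgCCAAT2a in sgCCAAT2b, and 78.7% of sgCCAAT2a and 76.8% of sgCCAAT2b in sgCtrl1. Between cell lines it gave 18.3% and 24.3% of RH4 NFYB in sgCtrl1 and sgCtrl2, and 14.7% and 11.8% conversely. Peaks that differ more than 2-fold in width cannot share 50% of both. This limits pairs of a wide RH4 NFYB peak with a narrow RH4 NFYC, consensus or RH30 entry, and the cause of the other falls was not tested.

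With the widest RH4 entries only, 86.7% of NFYB and 76.2% of NFYC peaks were shared and 82.1% and 80.6% lay at gene ends. The consensus then held 65% of endoplasmic reticulum, 15.9% of histone and 7.06% of ribosomal protein genes, and 0% of myogenic and of PAX3-FOXO1 target genes. Fewer entries leave fewer genes with a peak; the cause of the other shifts was not tested.

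With the first entries of the RH30 lists in file order, 89.8% of sgCtrl1 lay in sgCtrl2 and 54.1% of sgCtrl2 in sgCtrl1. Of sgCtrl2, 31.8% and 34.3% lay in sgCCAAT2a and sgCCAAT2b, and of sgCtrl1 53.0% and 56.6%. Of sgCCAAT2a 88.5% lay in sgCCAAT2b and 87.2% in sgCtrl1, and of sgCCAAT2b 89.1% in sgCtrl1. Gene-end shares rose to 76.8%, 72.3%, 74.9% and 74.9% for sgCtrl1, sgCtrl2, sgCCAAT2a and sgCCAAT2b, and histone genes with a peak in both controls fell to 11.6%. With both reductions, RH4 NFYB shared 78.5% with sgCtrl1 and 84.0% with sgCtrl2, 64.0% and 41.2% conversely. The cause was not tested. The PAX3 peak then stayed in 2 of the 4 lists that held it, sgCtrl1 and sgCtrl2; the RH4 NFYB and NFYC peaks, narrower than the median of their lists, fell out by construction.

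In the authors' deposited tables the shares listed over sgCCAAT2a, sgCCAAT2b and sgCtrl1 became 50.8%, 45.4% and 9.96% of the first 3343 sgCtrl2 peaks. Of sgCtrl2 peaks also in sgCtrl1 the authors' deposited tables listed 39.2%, 32.3% and 1.31%, and of those also in RH4 NFYB 44.6%, 36.5% and 1.92%. Of sgCtrl2 peaks also in sgCtrl1, 690 were listed over both edited libraries and not over sgCtrl1 in the authors' deposited tables. A window of 500 bp gave gene-end shares of 73.4% and 69.3% for RH4 NFYB and NFYC, and 49.3%, 39.7%, 57.0% and 56.2% for sgCtrl1, sgCtrl2, sgCCAAT2a and sgCCAAT2b, as a narrower window must hold fewer peaks.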

Other observations

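All tests in this part were chosen after the lists had been seen, except 3: the draws for myogenic genes, and the peak-by-peak and regional tests of histone genes, which were written down before their results.

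Gene families named by prefix were looked at beyond the fixed lists, and 6 were picked after seeing their shares among 93 prefixes with at least 20 members. Zinc finger genes named ZNF had a consensus peak in 117 of 517 cases, against a median of 69 in random lists and 74 in lists matched on gene density. RNA-binding genes named RBM had 17 of 47, against 6, and Mediator subunit genes 9 of 30, against 4. Collagen (0 of 44), keratin (0 of 55) and olfactory receptor genes (0 of 392) had none. Since they were picked for their shares, these percentages are not independent evidence.

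Single regions also stood out in RH30. OS9, a gene of endoplasmic reticulum quality control, had the peak at place 2, 51, 3 and 4 of the sgCtrl1, sgCtrl2, sgCCAAT2a and sgCCAAT2b lists. The region from 57 to 58.5 Mb of chromosome 12 around it, chosen after seeing the lists, held 23, 20, 10 and 9 peaks there, and 6 NFYB and 5 NFYC peaks in RH4. CDK4, in the same region, had a peak for NFYB in RH4 and in both RH30 controls (place 266 with sgCtrl1 and 199 with sgCtrl2) and in neither edited list, as PAX3 did. Unlike PAX3, it had no peak for NFYC in RH4. Copy number was not analysed here. Of peaks found in both controls and for NFYB in RH4, 365 of 2058 had no edited peak within 1000 bp. Among the 621 placed as high as PAX3 there were 7, which include CDK4, ANKRD39, DTYMK with ING5, COX14 with GPD1, ELL and PAX3. The targeted locus is therefore not the sole peak of high place missing from both edited lists. In the authors' deposited tables CDK4, DTYMK with ING5, ELL and PAX3 were also listed over both edited libraries. COX14 with GPD1 was listed over sgCCAAT2a only, and ANKRD39 over neither. Peaks from 34.5 to 34.7 Mb and from 46.3 to 46.5 Mb of chromosome 16 took 3 and 5 of the first 25 places in each edited list, 0 and 2 with sgCtrl2, and 0 and 0 with sgCtrl1. By count, the lower region held 1, 10, 11 and 10 peaks with sgCtrl1, sgCtrl2, sgCCAAT2a and sgCCAAT2b, and the upper 2, 9, 8 and 8. The RH4 NFYB and NFYC lists held 0 peaks in both regions. Whether these peaks are sites of NF-Y was not tested.

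The PAX3 peak, present in both controls and in neither edited list, may be missing because its CCAAT motif was edited, which is the biological explanation the design names. The place of the peak, 10.5% from the top of the sgCtrl2 list, argues against a weak control peak near the calling threshold only if file order ranks peaks. The headers do not state that it does, and this criterion was written after the place was known. Lower enrichment of all peaks in the edited libraries would remove some peaks at any place: 2.99% of comparable sgCtrl2 peaks within 250 places had no edited peak nearby. This ranged from 0 to 5.04% over the 6 neighbourhoods, and the bound set for excluding this explanation, under 5% in all 6, was missed in 1. Lower enrichment and editing therefore cannot be told apart for this single peak with 1 library per guide, although few comparable peaks were lost. Loss of edited reads in alignment was not tested.

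Most sgCtrl2 peaks were listed as higher than in each edited library, in the authors' deposited tables. In the last 3344 places, peaks particular to the sgCtrl2 library are a candidate explanation: 72.7% of the entries over sgCCAAT2a were also listed over sgCtrl1. Of all peaks in these places 62.5% were, so the share lies little above that of any peak there, and the shared sgCtrl2 library adds to it. In the first 3343 places 14.1% of the entries and 9.96% of all peaks were listed over sgCtrl1. Peaks particular to sgCtrl2 would be higher than in sgCtrl1 too, and most entries there did not pass the cutoffs over sgCtrl1. A peak can miss those cutoffs and still be absent from the sgCtrl1 list, as at CIC, SFXN5 and BCL2L1. Of the first 3343 sgCtrl2 peaks, 809 overlapped no peak of any other RH30 list. How many entries there are particular to sgCtrl2 therefore stays undecided. The share of tags in peaks with sgCtrl2 was 2.54 times that with sgCCAAT2a, but each share is summed over the library's own list and largely restates the number of peaks. Tags per called peak, per 10 M, were 46.4 with sgCtrl2, 59.6 with sgCtrl1, 49.8 with sgCCAAT2a and 57.1 with sgCCAAT2b, over unlike sets of peaks, so the controls lay on either side of the edited libraries. Neither decides whether enrichment was lower, and guide and library cannot be told apart with 1 library each. A wider effect of editing PAX3 on NF-Y binding stays open and untested.

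Histone genes looked protected: taking 1 gene for each of 16 distinct sgCtrl2 peaks left 1 gene absent, and 0.130% of draws of genes with a like place had as few. Followed peak by peak, over the 14 sgCtrl2 peaks that themselves overlapped an sgCtrl1 peak, the pattern ended, since 34.9% of draws had as few absent, so other peaks in the windows of these short, clustered genes are a candidate explanation. Of 7 control peaks elsewhere in the chromosome 6 histone span 0 were absent where 2.42 were expected, and 4.99% of draws had as few. This meets the bound written beforehand for a property of the region, under 5%, by less than the spread of the draws. That bound named no lowest count; with 7 peaks and fewer than 3 absent expected, a property of the region cannot be told apart from chance. No biological explanation was tested.

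The hypothesis that myogenic genes lost peaks beyond their weak place was left undecided: without PAX3, 13.0% of draws had as many absent. Deeper sequencing did not go with more peaks, as the RH30 library with the most peaks had the fewest tags, 10.5 M.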
